A study of Mus musculus with 15 samples.

How the data were processed

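RNA levels were measured in mammospheres, which are floating spheres of cells, grown from primary mammary tumour cells. The donor mice carried the polyoma middle T oncogene under the mouse mammary tumour virus promoter (MMTV-PyMT) on the FVB/N background. Per the labels' protocols, the cells were kept unattached and without serum, with EGF, FGF and B27. After 10 days an inhibitor or vehicle was added for 2 days, so each culture lasted 12 days. Total RNA was extracted with Trizol and purified on RNeasy columns, and 250 ng per sample was turned into biotin-labelled cRNA with a kit that primes at the 3′ end. Each of the 15 samples was hybridised to 1 Affymetrix Mouse430_2 array. Inhibitor doses are not given in the sources used here.

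The deposited values are signal intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes, they were made with Affymetrix Expression Console and MAS5, whose versions and settings are not given in the sources used here. The authors' scaling can be read from the values. On each array the mean intensity after trimming 2% at each end was 500. No detection calls were used here, so an array's own median served as the mark of a dim probe set. MAS5 sets each array to a common mean and not to a common distribution, so a shift of many genes in one direction can be hidden or spread over the other genes. Array medians ran from 65.7 to 90.8.

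The table held 45101 probe sets, of which 64 were controls. The platform annotation gave exactly 1 gene for 34945, several genes for 932 and no listed gene for 9160. Names were taken only from probe sets with 1 gene. Of these, 34741 were matched to the reference gene table by Entrez ID and 204 kept the annotation's symbol. No genome coordinates were used. Each of the 18193 genes was represented by its probe set with the highest mean log2 intensity over all arrays. A probe set whose name marks possible cross-hybridisation (ending in _x_at) was taken only where the gene had no other, which was so for 41 genes tested. A gene was tested if its probe set lay above the array median on at least 3 of the 15 arrays, which left 11412 genes.

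The 5 groups of 3 arrays came from the treatment labels. The log2 intensities were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, no pseudocount and no further normalization. Variances were moderated with an intensity trend, with 10 residual and 6.40 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini and Hochberg over the genes tested, with 0.05 as the threshold. Adjusted p-values of single genes below all come from this limma fit. The comparisons were each inhibitor against vehicle, the 3 contrasts among the kinase inhibitors, and an F-test over the 5 groups. The median standard error of a log2 fold change was 0.0976. The number of arrays limits the precision. The labels call the samples of a group biological replicates without saying whether these were separate mice or separate cultures, so the p-values measure the spread between these samples.

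Gene lists were fixed from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes. There were 26 lists with at least 5 tested members. Limma's camera test compared each list with the other genes, with a preset correlation between genes of 0.01. Its p-values were adjusted over 26 lists and the 4 comparisons against vehicle. Adjusted p-values of lists below come from this test with the preset correlation unless another is named, and their size rests on that value. With a correlation estimated from the data, fewer lists were called in each comparison. The same test of the 3 contrasts among kinase inhibitors was added after the data had been seen and was adjusted as a family of its own. Named genes were the 8 largest rises and 8 largest falls of each comparison against vehicle and of TAE226 against PP2, together with members of the lists described. The first kind had to pass the threshold, to have groups whose arrays did not overlap, and to lie above the array median on all arrays of the brighter group. From each list at most 4 members past the threshold with the greatest change were taken. A few genes outside this rule are named as such. Where every array of a group lay below its median, the gene is called dim there. The fold is then a lower bound, for which each dim array was set at the higher of its median and the gene's own value. List medians with dim members held at that bound are given for most printed medians that moved.

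Replicates were compared before they were averaged. Within groups, the median absolute log2 difference between 2 arrays was 0.119 to 0.173, and between groups it was 0.187 to 0.395. At most 2 probe sets had the same value on a pair of arrays, so no array was a copy of another. RNA quality was read from the control probe sets at the 3′ and 5′ ends of actin and Gapdh. The order of the arrays followed the groups, so any trend with processing order and the treatment cannot be told apart.

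The procedure was tested on simulated data made from the 11412 genes' own means and spread, with 50 genes changed at each size. For DAPT against vehicle, 94% of genes changed 2-fold, 72% of those changed 1.5-fold and 52% of those changed 1.25-fold were recovered, with 7 false calls. For U0126 these shares were 90%, 58% and 34% with 12 false calls, for TAE226 82%, 62% and 36% with 5, and for PP2 88%, 68% and 32% with 5. A simulated list of 15 genes shifted 1.5-fold was called in each, and 0 unshifted lists were. The simulated genes varied independently and their lists were drawn at random, so this does not test the preset correlation on real lists. Far fewer genes were changed than were called in the data, so the shares recovered may differ there.

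The alternatives tried were quantile normalization, centring each array on its median, and pseudocounts of 20.6 (the 25th percentile of the signals) and 80.7 (their median). Dim genes were also tested without a filter and with a stricter one at the 60th percentile. Other fits had no intensity trend, robust variances, array weights, only the groups compared, the replicate number as a block, or each array left out in turn. Genes were also represented by the mean of their probe sets, probe sets were tested singly, and a threshold of at least 2-fold was set. Lists were tested with an estimated correlation and with fry, which asks whether a list moves on balance and not whether it moves more than other genes. Comparisons against vehicle share its 3 arrays, so overlaps are given beside 50 simulations of unchanged groups (seed 1). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.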

Results

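Gene expression was measured in 15 mammosphere cultures of primary mammary tumour cells from MMTV-PyMT mice. The cultures formed 5 groups of 3 biological replicates, which received vehicle or a signalling inhibitor for 2 days. DAPT inhibits γ-secretase, the protease that frees the active part of Notch receptors. U0126 inhibits MEK1, the kinase that activates ERK, TAE226 inhibits focal adhesion kinase (FAK) and PP2 inhibits Src family kinases. The study's title concerns the tyrosine phosphatase Shp2 and its suppression of senescence, and the comparisons ask which genes change under each inhibitor. Effects of these compounds on other proteins were not tested. Values are MAS5 signals on the log2 scale, and fold changes are inhibitor over vehicle unless another pair is named. Median signals per array ran from 65.7 to 90.8.

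The 5 treatments were separated from each other by more than the spread between replicates. The first 2 principal components held 36.4% and 22.7% of the variance, with PP2 at one end of the first component and U0126 opposite vehicle on the second. Spearman correlations across genes were 0.953 to 0.967 within groups and 0.937 to 0.965 between groups. Of the 11412 genes tested, 8351 (73.2%) differed among the 5 groups by limma's F-test. The ratio of actin signal at the 3′ end to that at the 5′ end, which rises as RNA is shortened, was 1.57 ± 0.04 in PP2, 1.42 ± 0.06 in vehicle and 1.28 ± 0.07 in U0126 (SD, n = 3 each).

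**Figure D1:**
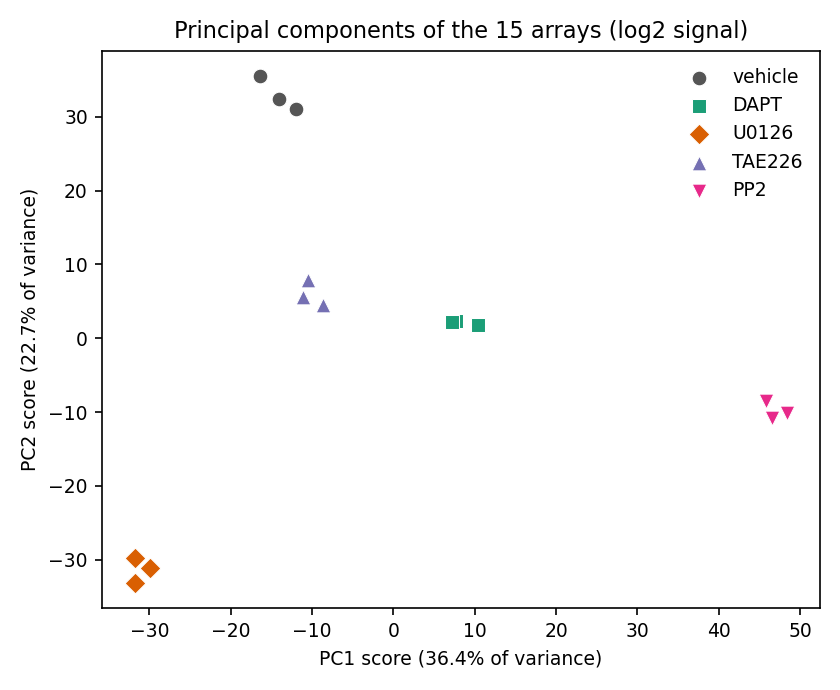
Scores of the 15 arrays on the first principal component (horizontal, 36.4% of variance) and the second (vertical, 22.7%), computed from log2 signals. Each point is 1 array, coloured and shaped by treatment, and the 3 arrays of each group lie closer to each other than to any other group.

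Under DAPT, genes of the Notch pathway fell. Nrarp, a target of Notch that feeds back on it, went from a mean log2 signal of 9.15 ± 0.18 in vehicle to 6.41 ± 0.38 (SD, n = 3 each; log2 fold change −2.74, SE 0.20, adjusted p = 1.43e-08). Hes1, a transcriptional repressor that Notch induces, went from 10.48 ± 0.18 to 9.22 ± 0.11 (−1.26, SE 0.09, adjusted p = 1.91e-08). Of 9 Notch targets tested 5 fell, Hey1 (−1.19) and the ligand Jag1 (−1.14) among them, 1 rose and 3 did not pass (list adjusted p = 0.00108). Jag1, however, was called lower under each of the other inhibitors too, although the Notch list was not called under U0126 or PP2. All 14 interferon response genes fell, with a median log2 fold change of −4.19, or −3.02 with 4 dim members held at their bound (adjusted p = 3.1e-17). Rsad2, an antiviral enzyme, went from 12.61 ± 0.21 to 7.28 ± 0.11 (−5.33, SE 0.21, adjusted p = 5.3e-12). Ifit1, which binds foreign RNA, changed by −5.60, and the antiviral genes Oasl2 and Mx2 fell at least 16.8-fold and at least 5.57-fold to a dim level.

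Genes of the cell cycle and of stress responses also fell under DAPT. Of 24 G2/M and mitosis genes 21 fell (median −0.74, adjusted p = 4.19e-12), among them the ubiquitin-conjugating enzyme Ube2c (−1.02) and the kinase Plk1 (−0.88). Of 22 G1/S and replication genes 13 fell, such as Uhrf1 (−0.80) and the licensing factor Cdc6 (−0.76), and 9 did not pass (adjusted p = 8e-05, and 0.104 with an estimated correlation). Of 16 hypoxia and glycolysis genes 12 fell (adjusted p = 2.15e-08), led by the vasodilator peptide Adm (−2.47) and the hypoxia-induced Ankrd37 (−1.56). Of 17 genes of the unfolded protein and integrated stress response 13 fell (adjusted p = 1.27e-08), with Ddit3, the stress transcription factor CHOP, at −2.07 and the pseudokinase Trib3 at −1.81. Of 16 cholesterol synthesis genes 9 fell, Cyp51 by −0.57 (adjusted p = 0.000191, and 0.0614 with an estimated correlation). Of 17 ERK outputs 7 fell, the ERK phosphatase Dusp4 by −1.54 (adjusted p = 0.0125).

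Basal, milk and adhesion genes rose under DAPT. Of 11 basal and myoepithelial markers 5 rose and 1 fell (adjusted p = 0.0022), among them the oxytocin receptor Oxtr (2.47, SE 0.07, adjusted p = 1.29e-13) and the basal transcription factor Trp63 (1.14). The basal keratin Krt15 went from 7.84 ± 0.03 to 11.81 ± 0.04 (3.97, SE 0.45, adjusted p = 2.67e-06). Of 14 YAP and SRF targets 9 rose and 1 fell, the cytoskeletal adaptor Ajuba by 1.10 (adjusted p = 0.00021). Of 16 milk and alveolar genes 9 rose, such as the amino acid oxidase Lao1 (1.59) and lactoferrin, Ltf (1.44), and 2 fell (median 0.67, or 0.62 with the dim member at its bound). Its adjusted p was 0.00497, and 0.127 with an estimated correlation. Of 17 focal adhesion and integrin genes 9 rose, Parva by 0.73, although its other bright probe set went the other way, and 1 fell (adjusted p = 0.00298, and 0.127 with an estimated correlation). FOXO targets (8 of 13 rose, 2 fell, Fbxo32 1.34) and AHR targets (2 of 5 rose, Aldh3a1 2.03) had adjusted p = 0.0475 and 0.0421, and adjusted p = 0.154 and 0.244 with an estimated correlation. Median centring took the medians from 0.33 to 0.20 for basal markers, 0.34 to 0.21 for YAP and SRF targets, 0.24 to 0.11 for focal adhesion, 0.29 to 0.16 for FOXO and 0.37 to 0.24 for AHR targets. Without the member dim in both groups the AHR median was 0.45. The FOXO call ended without vehicle replicate 3 (adjusted p = 0.0933), DAPT replicate 1 (0.0541) or DAPT replicate 2 (0.0933). The AHR call ended without vehicle replicate 2 (0.0946, median −0.09) or DAPT replicate 1 (0.0843, median −0.08), and also with a pseudocount at the median signal (0.0561) or no filter on dim genes (0.115). The greatest rises of single genes held the chemokine Ccl6 (4.32, SE 0.17, adjusted p = 4.86e-12) and the matrix proteoglycan Ogn (3.15, SE 0.07, adjusted p = 1.47e-14).

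In all, DAPT called 3948 genes, 1950 higher and 1998 lower, of which 434 changed at least 2-fold (184 higher, 250 lower). Groups did not overlap in 46.5% of genes, against 10% by chance. With arrays centred on their medians the split was 689 higher and 2444 lower. Adjusted over the list alone, the counts were 22 for G2/M, 14 for G1/S, 14 for the unfolded protein response, 13 that fell and 1 that rose for hypoxia, 10 that rose and 3 that fell for milk, and those above for the other lists described. The 15 lists called held 9 with an estimated correlation. Among the lists not called, adjusted p ran from 0.0809 for EMT genes, which were called with quantile normalization (0.0488) and median centring (0.0491), to 0.999 for p53 targets, and it was 0.119 for immediate early genes, 0.176 for stem cell markers, 0.298 for NRF2 targets, 0.514 for luminal markers, 0.582 for ERBB ligands and receptors, 0.596 for keratinization and 0.876 for the BCL2 family.

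Under U0126, outputs of the ERK pathway fell. Egr1, a transcription factor induced by ERK within minutes, went from 13.18 ± 0.10 in vehicle to 10.08 ± 0.13 (−3.11, SE 0.09, adjusted p = 6.57e-14, n = 3 each, limma). The phosphatase Dusp6, which switches ERK off, went from 13.07 ± 0.05 to 11.07 ± 0.12 (4-fold lower, SE of the log2 fold change 0.06, adjusted p = 6.75e-14). Of 17 ERK outputs 9 fell, the transcription factor Etv5 by −1.69 among them, 1 rose and 7 did not pass (median −0.85, adjusted p = 0.000281). Of 9 immediate early genes 6 fell, such as Ier2 (−1.29) and Fos (−1.21), and 1 rose (adjusted p = 0.00268).

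Targets of the aryl hydrocarbon receptor (AHR) and of NRF2, which control enzymes that handle foreign and oxidising compounds, rose under U0126. All 5 AHR targets rose, with a median of 5.63, also with the dim member at its bound (adjusted p = 2.45e-10). Cyp1b1, an oxidase of aromatic compounds, went from 8.42 ± 0.07 to 14.05 ± 0.12 (5.63, SE 0.07, adjusted p = 4.77e-19). Its relative Cyp1a1 was dim in vehicle and rose at least 56.9-fold (adjusted p = 7.75e-10), and the aldehyde dehydrogenase Aldh3a1 rose by 6.15 (SE 0.08). Of 10 NRF2 targets 9 rose (median 0.85, adjusted p = 1.27e-08), led by the glutathione transferase Gsta4 (3.05) and the quinone reductase Nqo1 (2.66), which is also an AHR target. Of 14 YAP and SRF targets 10 rose and 1 fell (median 0.85, or 0.92 without the member dim in both groups; adjusted p = 1.62e-07), with Ankrd1 at 2.09 and the matrix protein Ccn1 at 1.75. Of 20 p53 targets 11 rose and 1 fell (adjusted p = 0.000103), among them the death receptor Fas (1.17) and the antiproliferative gene Btg2 (0.99). Of 6 EMT genes 4 rose, fibronectin, Fn1, by 2.52 and the cadherin Cdh2 by 1.78, and 2 fell (adjusted p = 0.0256, and 0.0705 with an estimated correlation).

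Milk, interferon and stress genes fell under U0126. The casein Csn1s1 went from 12.43 ± 0.05 to 7.17 ± 0.26 (−5.25, SE 0.09, adjusted p = 1.32e-16), and of 16 milk and alveolar genes 10 fell, lactoferrin (Ltf) by −1.94 among them, and 1 rose. Their median was −0.87, or −0.52 with 3 dim members at their bound and 1 dim in both groups left out (adjusted p = 1.37e-05), and the actin ratio was 1.28 ± 0.07, against 1.42 ± 0.06 in vehicle. All 14 interferon response genes fell (median −3.47, or −2.82 with 4 dim members at their bound; adjusted p = 5.39e-13), Ifit1 by −4.35. Of 17 unfolded protein and integrated stress response genes 14 fell, such as Trib3 (−1.59) and Ddit3 (−1.35), and 1 rose (adjusted p = 2.14e-07). Of 16 cholesterol synthesis genes 9 fell, Cyp51 by −0.80 (adjusted p = 0.0191, and 0.218 with an estimated correlation). The greatest single changes held rises of the proteolipid Mal (6.45, SE 0.15, adjusted p = 2.96e-15, from 7.29 ± 0.18 to 13.73 ± 0.14) and the transcription factor Sox11 (4.47), and falls of the glutamate decarboxylase Gad1 (at least 4.3-fold, dim under U0126) and the bone matrix protein Dmp1 (at least 16-fold).

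Cell cycle lists were not called under U0126. Of 24 G2/M and mitosis genes 3 rose, 1 fell and 20 did not pass (median −0.01, mean −0.01, though the test pointed up; adjusted p = 0.999). These were Aurka (0.29), Cdk1 (0.28), Ccnb2 (0.26) and Mki67 (−0.39). Each of these calls ended when a single array was left out. Aurka did not pass without vehicle replicate 1 (adjusted p = 0.0739) or U0126 replicate 1 (0.0542), nor did Cdk1 without vehicle replicate 2 (0.0812) or U0126 replicate 1 (0.0663), nor Mki67 without vehicle replicate 3 (0.0558). Ccnb2 did not pass without vehicle replicate 1 (0.061) or 2 (0.08), or U0126 replicate 1 (0.0708) or 2 (0.0563). With median centring Aurka (0.188), Cdk1 (0.201) and Ccnb2 (0.206) did not pass either. Of 22 G1/S and replication genes 3 rose and 8 fell, Cdc6 by −0.87 (adjusted p = 0.106).

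In all, U0126 called 4663 genes, 2222 higher and 2441 lower, of which 650 changed at least 2-fold (320 higher, 330 lower). Groups did not overlap in 48.3% of genes, against 10% by chance. With median centring the split was 1211 higher and 2424 lower. Adjusted over the list alone, 11 ERK outputs and 11 milk genes fell, 12 p53 targets rose and 2 unfolded protein response genes rose, and the other counts were those above. The 11 lists called held 9 with an estimated correlation. Of the lists not called, the adjusted p was 0.187 for basal markers, 0.209 for the BCL2 family, 0.246 for FOXO targets, 0.263 for focal adhesion, 0.269 for hypoxia, 0.35 for keratinization, 0.462 for Notch targets, 0.555 for luminal markers, and 0.876 for both stem cell markers and ERBB ligands and receptors.

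Under TAE226, hypoxia and glycolysis genes fell as a group, all 16 of 16 tested (median −1.14, adjusted p = 8.4e-19). Egln3, an oxygen-sensing prolyl hydroxylase, went from 11.36 ± 0.05 in vehicle to 7.97 ± 0.18 (−3.38, SE 0.12, adjusted p = 1.23e-11, n = 3 each, limma), and the carbonic anhydrase Car9 fell with a log2 fold change of −2.02. Of 16 cholesterol synthesis genes 15 fell (median −0.49, adjusted p = 2.68e-10), Cyp51 by −0.86 and Insig1 by −0.73. All 14 interferon response genes fell (median −2.13, or −2.08 with 2 dim members at their bound; adjusted p = 4.41e-11), Rsad2 by −2.77 (SE 0.21). Of 17 unfolded protein and integrated stress response genes 13 fell, Trib3 by −1.66, and 1 rose (adjusted p = 7.13e-10).

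Targets of YAP, SRF and p53 rose under TAE226. Of 14 YAP and SRF targets 11 rose and 1 fell (median 0.83, or 0.77 with the dim member at its bound; adjusted p = 1.19e-08), Ankrd1 by 2.35 and the kinase Lats2 by 1.12. Of 20 p53 targets 14 rose and 0 fell (median 0.37, adjusted p = 1.05e-08), such as Sesn2 (0.79) and Mdm2 (0.75), the ligase that degrades p53. The median of the p53 targets was 0.12 with median centring, while their list was still called (adjusted p = 1.92e-07). Of 6 EMT genes 5 rose, Cdh2 by 2.20 and Fn1 by 1.73 (adjusted p = 0.000496). Of 17 focal adhesion and integrin genes, the list nearest to FAK itself, 8 rose and 2 fell, with the integrin Itgb6 at 0.96 and the adaptor Bcar1 at 0.66 (adjusted p = 0.00536, and 0.15 with an estimated correlation). Their median was 0.27, or 0.29 with the dim member at its bound. In the BCL2 family 4 of 12 genes rose and 0 fell (adjusted p = 0.00533), but its median of 0.19 became −0.06 with median centring, as that of focal adhesion genes went from 0.27 to 0.01 and that of EMT genes from 0.48 to 0.23. Under that setting the BCL2 members Bik (0.75) and Bid (0.37) no longer passed (adjusted p = 0.086 and 0.4).

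Cell cycle genes fell under TAE226, 20 of 24 of the G2/M and mitosis list (median −0.51, adjusted p = 3.74e-09, and adjusted p = 0.0846 with an estimated correlation). The proliferation marker Mki67 changed by −0.88 and the survival protein Birc5 by −0.73. Of 22 G1/S and replication genes 9 fell, Uhrf1 by −0.68 (adjusted p = 0.00261, and 0.212 with an estimated correlation). Of 9 Notch targets 5 fell, Hey1 by −1.26 and Jag1 by −1.18, and 1 rose (adjusted p = 0.016, and 0.0809 with an estimated correlation). Of 17 ERK outputs 7 fell, Etv5 by −0.87 (adjusted p = 0.00696). The greatest rises of single genes held Pappa, a protease of insulin-like growth factor binding proteins (3.23, SE 0.16, adjusted p = 2.94e-10, from 7.33 ± 0.26 to 10.56 ± 0.07), and Foxj1, a transcription factor of motile cilia (2.93, SE 0.12, adjusted p = 2.54e-11). The protease Klk7, dim in vehicle, rose at least 1.98-fold (adjusted p = 0.016) but did not pass without vehicle replicate 1 (0.0798) or TAE226 replicate 2 (0.0531).

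In all, TAE226 called 3548 genes, 1732 higher and 1816 lower, of which 322 changed at least 2-fold (173 higher, 149 lower). Groups did not overlap in 43.3% of genes, against 10% by chance. With median centring the split was 428 higher and 4241 lower. Adjusted over the list alone, counts rose to 21 for G2/M, 11 that fell and 1 that rose for G1/S, 14 that fell for the unfolded protein response, 12 that rose for YAP and SRF targets, 10 that rose for focal adhesion, 5 for the BCL2 family and 2 that rose for ERK outputs. Those of the other lists described were as above. The 13 lists called held 9 with an estimated correlation. Of the lists not called, the adjusted p was 0.0765 for NRF2 targets (0.0498 without TAE226 replicate 2), 0.0828 for milk genes, 0.149 for FOXO targets, 0.168 for AHR targets and 0.194 for keratinization (0.0173 and 0.0305 with median centring), 0.22 for immediate early genes, 0.35 for ERBB ligands and receptors, 0.437 for luminal markers, 0.587 for basal markers and 0.889 for stem cell markers.

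Under PP2, milk genes rose and cell cycle genes fell, on arrays whose actin 3′ to 5′ ratio (1.57 ± 0.04, n = 3) exceeded that of vehicle (1.42 ± 0.06, n = 3). The milk protein Csn2 went from 6.48 ± 0.09 in vehicle to 13.28 ± 0.13, a 112-fold rise (log2 fold change 6.80, SE 0.18, adjusted p = 5.66e-14). Its vehicle level lay close to the array medians (log2 6.04 to 6.50 over all arrays), so the size of that fold is uncertain. The casein Csn1s1, already at 12.43 ± 0.05, reached 14.80 ± 0.05 (2.37, SE 0.09, adjusted p = 2.71e-12). Of 16 milk and alveolar genes 12 rose, 1 fell and 3 did not pass (median 1.06, adjusted p = 1.51e-06). Of 24 G2/M and mitosis genes 23 fell (median −1.46, adjusted p = 2.38e-14), among them the checkpoint kinase Bub1 (−1.77) and the spindle protein Nusap1 (−1.72). Of 22 G1/S and replication genes 20 fell (median −0.90, adjusted p = 2.66e-09), Uhrf1 by −1.78 and the helicase subunit Mcm5 by −1.47.

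ERK outputs, ERBB ligands and mesenchymal genes fell under PP2, on the same arrays with the raised actin ratio. Of 17 ERK outputs 16 fell (median −0.99, or −0.92 with 3 dim members at their bound; adjusted p = 1.58e-08), Etv5 by −2.46 and Dusp6 by −1.93. Of 9 immediate early genes 6 fell, Egr1 by −1.37 and Junb by −0.88, and 1 rose (adjusted p = 0.0044). Of 9 ERBB ligands and receptors 5 fell and 3 rose (adjusted p = 0.0369, and 0.0809 with an estimated correlation). Those that fell held the growth factors Hbegf (−2.36) and Ereg (−2.15), and those that rose were the receptors Egfr (0.26), Erbb2 (0.30) and Erbb3 (0.21), which were chosen after their values were seen and did not pass with median centring (0.04, 0.08 and −0.01). The ERBB call also ended with the stricter filter on dim genes (adjusted p = 0.0508). Of 6 EMT genes 5 fell, S100a4 by −2.36 and Sparc by −1.63, and 1 rose (adjusted p = 0.00628). Postn, from the list of fibroblast markers, fell on the same arrays (−5.30), as described below. Of 11 basal and myoepithelial markers 8 fell, the keratin Krt5 by −1.20, and 1 rose (median −0.78, or −0.70 with 1 dim member at its bound and 1 dim in both groups left out; adjusted p = 0.00866).

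Interferon, hypoxia and metabolic genes also fell under PP2. All 14 interferon response genes fell (median −4.01, or −2.83 with 6 dim members at their bound; adjusted p = 8.97e-11), Rsad2 by −5.72 (SE 0.21) and Ifit1 at least 40.4-fold to a dim level. Of 16 hypoxia and glycolysis genes 13 fell, Egln3 by −3.67 and Car9 by −3.12, and 2 rose (median −1.11, adjusted p = 1.44e-07). Of 16 cholesterol synthesis genes 15 fell, Cyp51 by −1.36 (adjusted p = 1.52e-08). Of 17 unfolded protein and integrated stress response genes 11 fell, Trib3 by −2.69, and 1 rose (adjusted p = 3.69e-05). The lists nearest to Src were not called. Of 17 focal adhesion and integrin genes 5 rose, Bcar1 by 0.81, and 3 fell, with a median of −0.03 and a mean of 0.11 in the direction of the test (adjusted p = 0.48). Median centring moved every fold change under PP2 by −0.219, so this mean turned negative. Of 14 YAP and SRF targets 7 rose, Ankrd1 by 1.03, and 5 fell, Ccn2 by −0.90. The median was 0.24, or 0.22 without the member dim in both groups, and the mean was 0.03, although the test pointed down (adjusted p = 0.998). With median centring this mean turned negative as well.

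In all, PP2 called 6030 genes, 2978 higher and 3052 lower, of which 1040 changed at least 2-fold (438 higher, 602 lower). Groups did not overlap in 59.0% of genes, against 10% by chance. With median centring the split was 1210 higher and 4331 lower. Adjusted over the list alone, 2 basal markers and 8 YAP and SRF targets rose, and the other counts were those above. The 13 lists called held 11 with an estimated correlation. Of the lists not called, the adjusted p was 0.0504 for stem cell markers (0.0337 without vehicle replicate 3, 0.0398 without PP2 replicate 2 and 0.0434 without PP2 replicate 3), 0.113 for FOXO targets, 0.155 for the BCL2 family, 0.233 for luminal markers, 0.28 for NRF2 targets, 0.321 for Notch targets, 0.464 for AHR targets and 0.885 for keratinization.

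**Figure D2:**
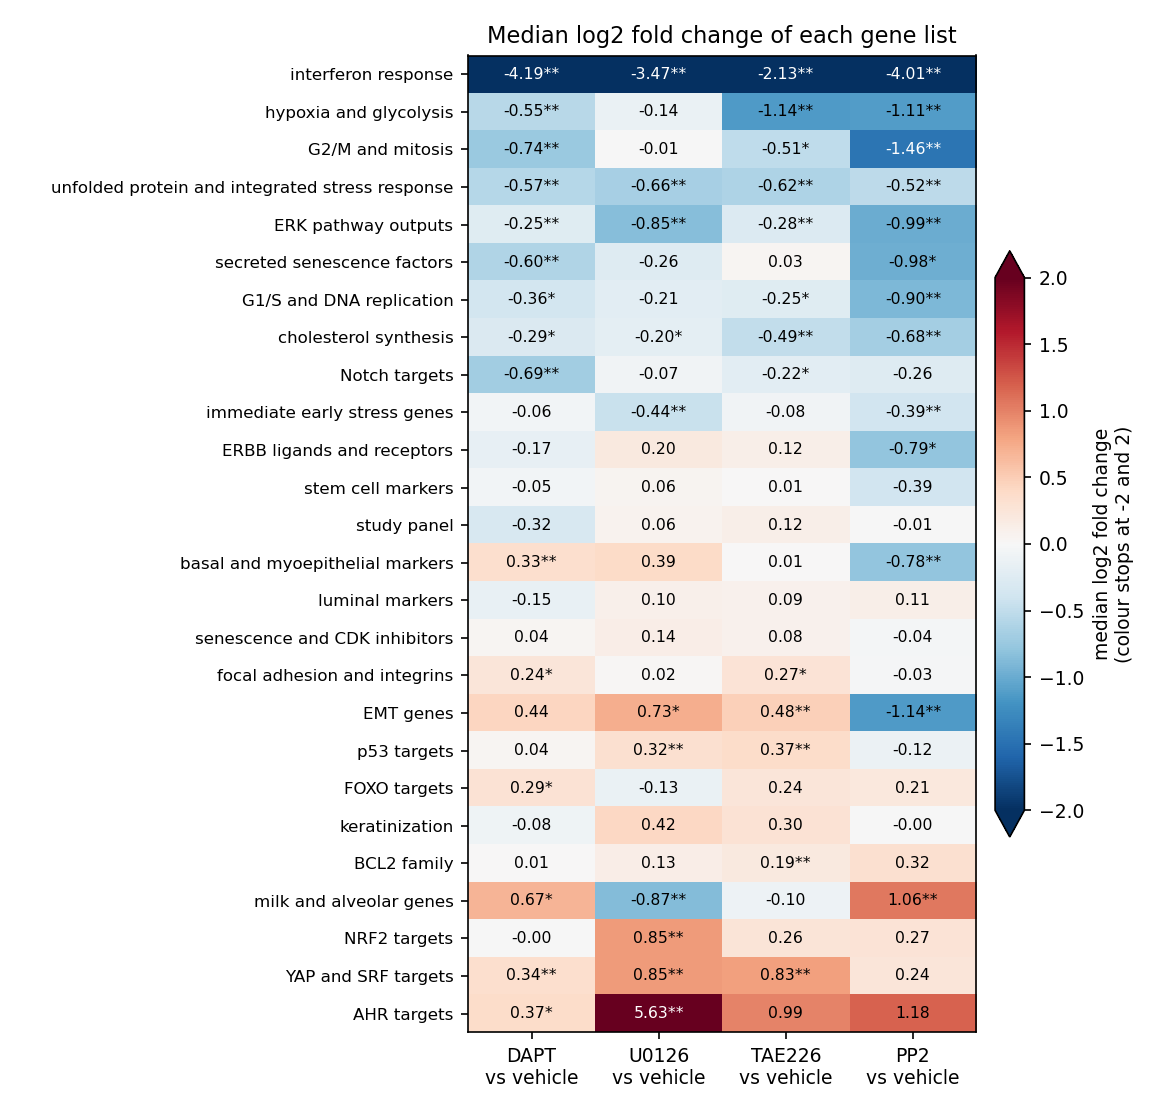
Median log2 fold change (colour and printed value) of the tested members of 26 gene lists, 1 line each, in the 4 comparisons against vehicle, with colours that stop at −2 and 2. 1 asterisk marks a list called by camera with the preset correlation and a pair of asterisks a list also called with an estimated correlation, and interferon response genes are lowest in all 4 columns (−4.19, −3.47, −2.13 and −4.01).

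The list of senescence genes and CDK inhibitors was not set apart from other genes by camera under DAPT (2 of 14 rose, 4 fell, adjusted p = 0.514), U0126 (7 rose, 5 fell, adjusted p = 0.61), TAE226 (2 rose, 4 fell, adjusted p = 0.774) or PP2 (5 rose, 5 fell, adjusted p = 0.592). Fry, which asks only whether a list moves on balance, called it in all 4 (adjusted p = 4.69e-06, 0.0392, 0.000823 and 2.5e-08 in the same order). Adjusted over the list alone the counts differed for DAPT (5 fell) and TAE226 (5 rose). Under DAPT its median was 0.04 while the mean (−0.16) and the test pointed down, and under U0126 its median (0.14) and the test pointed up while the mean was −0.03. Under TAE226 the median of 0.08 became −0.17 with median centring. The promyelocytic leukaemia gene Pml, which belongs to this list and is also induced by interferon, fell under all 4 inhibitors (−1.06, −1.63, −0.74 and −1.15 for DAPT, U0126, TAE226 and PP2). Igfbp7, a secreted protein that binds insulin-like growth factors, rose under TAE226 (1.94) and fell under PP2 (−1.78).

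Secreted senescence factors fell under DAPT, 5 of 11 tested, and 6 with 1 that rose when adjusted over the list alone (median −0.60, or −0.48 with dim members at their bound; adjusted p = 0.00189). Under PP2, 7 fell and 2 rose (median −0.98, or −0.75 with dim members at their bound; adjusted p = 0.00448, and 0.055 with an estimated correlation), and the actin ratio was raised on those arrays. The chemokine Cxcl2 fell at least 7.9-fold under DAPT and at least 7.44-fold under PP2 to a dim level, and Cxcl1 changed by −1.27 and −2.03. The list was not called under U0126 (3 rose, 3 fell, adjusted p = 0.751). Under TAE226 1 rose and 4 fell (adjusted p = 0.271), with a mean of −0.24 and a test that pointed down. The median was 0.03, or 0.09 with dim members at their bound, and it was −0.01 with quantile normalization and −0.22 with median centring. These counts were the same for U0126, TAE226 and PP2 when adjusted over the list alone. Targets of p53 were not called under DAPT (3 rose, 4 fell, adjusted p = 0.999) or PP2 (3 rose, 9 fell, adjusted p = 0.129), where adjustment over the list alone gave 4 that rose in each.

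A panel of 7 tested genes that the study is known to follow was examined one by one. It may have been chosen on these samples, so its counts are not independent evidence, and it was not called as a list (adjusted p = 0.155 for DAPT, 0.514 for U0126, 0.977 for TAE226 and 0.321 for PP2). It held 2 rises and 4 falls under DAPT, 3 and 1 under U0126, 2 and 3 under TAE226, and 2 and 3 under PP2. Adjusted over the list alone, falls under DAPT were 5 and rises under TAE226 4. Skp2, which targets CDK inhibitors for degradation, fell under PP2 (−0.76, adjusted p = 1.66e-07), DAPT (−0.32, adjusted p = 0.00246) and TAE226 (−0.26, adjusted p = 0.0103), and was at 0.01 under U0126 (adjusted p = 0.955). Of its 5 other bright probe sets, 3 or 4 went the same way in each comparison, and as the mean of its probe sets it did not pass under DAPT (adjusted p = 0.0913) or TAE226 (0.0656). The CDK inhibitor p21, Cdkn1a, fell under PP2 (−1.01, adjusted p = 6.41e-10) and DAPT (−0.79, adjusted p = 4.29e-08), and rose under TAE226 (0.30, adjusted p = 0.00142) and U0126 (0.21, adjusted p = 0.0126). Without U0126 replicate 2 the U0126 rise was 0.14 (adjusted p = 0.0791), and with median centring the rises were 0.13 and 0.05 for U0126 and TAE226 and did not pass.

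Cdkn1b, the CDK inhibitor p27, fell under U0126 (−0.64, adjusted p = 7.43e-08), TAE226 (−0.61, adjusted p = 2.9e-07) and DAPT (−0.48, adjusted p = 3.64e-06), but its other bright probe set went up under U0126 and TAE226, and as the mean of its probe sets it did not pass under TAE226 (adjusted p = 0.765). It rose under PP2 (0.27, adjusted p = 0.000487), where median centring left 0.05. Cdkn2a rose under U0126 (0.71, adjusted p = 7.59e-06) and DAPT (0.37, adjusted p = 0.00433), the latter not passing with median centring (0.24), and was at 0.23 under TAE226 (adjusted p = 0.0673) and −0.01 under PP2 (adjusted p = 0.919). Median centring moved every fold change under TAE226 by −0.254, so the TAE226 value of Cdkn2a turned negative. The Notch ligand Dll1 rose under DAPT (0.77, adjusted p = 6.34e-08). Its rises under PP2 (0.30, adjusted p = 0.000689) and TAE226 (0.25, adjusted p = 0.0056) became 0.08 and −7e-04 with median centring. The mitotic kinase Aurka fell under PP2 (−1.09, adjusted p = 2.76e-08) and DAPT (−0.46, adjusted p = 0.000839), the latter not passing as the mean of its probe sets (adjusted p = 0.135). Its fall under TAE226 (−0.26, adjusted p = 0.0356) did not pass without vehicle replicate 2 (0.132) or 3 (0.0772), or TAE226 replicate 2 (0.108) or 3 (0.0797). Ptpn11, which encodes Shp2, passed in none of the 4 comparisons (−0.12, 0.06, 0.12 and 0.03 for DAPT, U0126, TAE226 and PP2, with adjusted p = 0.109, 0.382, 0.11 and 0.72). Without TAE226 replicate 1 its TAE226 value was 0.18 (adjusted p = 0.0186), and it also passed with quantile normalization (0.0343), array weights (0.0256) and the mean of its probe sets (0.0225). With median centring, however, its TAE226 value turned negative, as the shift of −0.254 exceeds it in size.

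**Figure D3:**
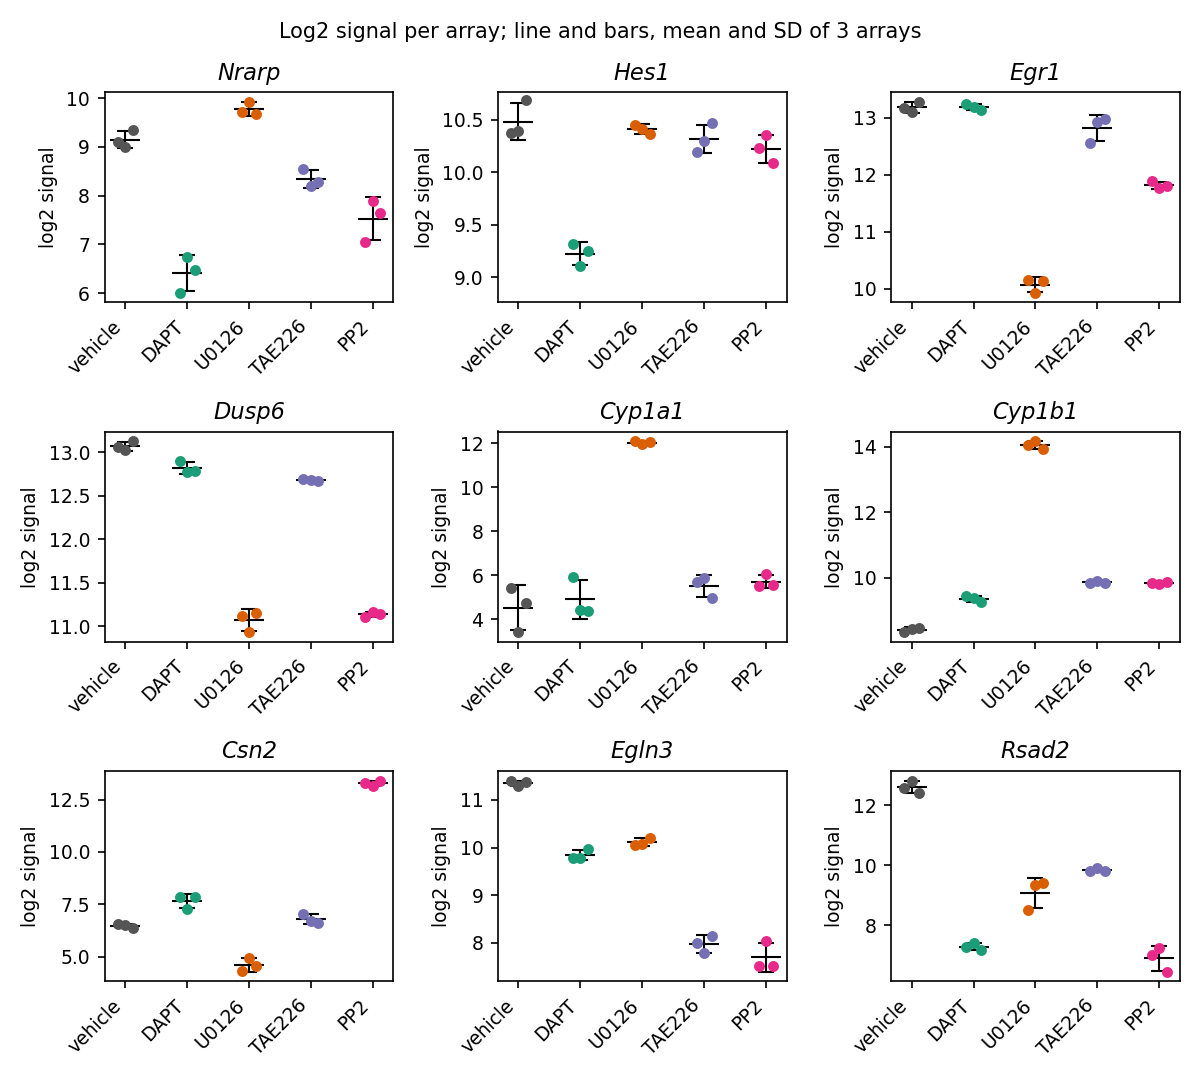
Log2 signal (vertical axis, a separate scale in each panel) of 9 genes on each of the 15 arrays, by treatment. Points are arrays, and the line and bars are the mean and SD of 3 arrays. Nrarp and Hes1 are lowest under DAPT, Egr1 under U0126, and Csn2 is highest under PP2 (13.28).

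TAE226 and PP2, given against kinases that act together at focal adhesions, differed from each other in 4975 genes, of which 2650 were higher and 2325 lower under TAE226, or 1786 and 1958 with median centring, and 809 differed at least 2-fold (503 higher, 306 lower). The matrix protein periostin, Postn, was at 13.96 ± 0.04 under TAE226 and 8.52 ± 0.26 under PP2 (5.44, SE 0.09, adjusted p = 7.56e-17, n = 3 each), and the metalloprotease Adam12 was 24.3-fold higher (SE of the log2 difference 0.10, adjusted p = 2.71e-15). Csn2 was lower under TAE226 (−6.48, SE 0.18, adjusted p = 1.4e-13), as was the secreted glycoprotein Lrg1 (−4.39, SE 0.38, adjusted p = 6.68e-08). Of 24 G2/M genes 23 were higher under TAE226 (median 0.93, adjusted p = 9.88e-12), as were 18 of 20 p53 targets (median 0.55, adjusted p = 1.98e-08), 14 of 17 ERK outputs with 1 lower (median 1.03, or 0.76 with dim members at their bound; adjusted p = 2.13e-07), 12 of 14 interferon genes (adjusted p = 5.17e-07) and 5 of 6 EMT genes (adjusted p = 1.31e-05). Of 16 milk genes 12 were lower, and 14 when adjusted over the list alone (adjusted p = 7.2e-10). The other counts were the same over the list alone. Hypoxia genes were not shown to differ (4 higher, 4 lower, adjusted p = 0.932). The actin ratio was 1.33 ± 0.07 under TAE226 and 1.57 ± 0.04 under PP2. Of 13 lists called 11 held with an estimated correlation.

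U0126 and TAE226 differed in 4249 genes, 2025 higher and 2224 lower under U0126, or 2984 and 765 with median centring. At least 2-fold differences were 426 (166 higher, 260 lower). All 16 hypoxia genes were higher under U0126 than under TAE226 (median 1.04, adjusted p = 3.29e-15), Egln3 by 2.14, and 19 of 24 G2/M genes were higher (adjusted p = 2.69e-08, and 0.101 with an estimated correlation). Of 17 ERK outputs 9 were lower and 2 higher (median −0.44, or −0.40 with the dim member at its bound; adjusted p = 0.0029). U0126 and PP2 differed in 6375 genes, 3176 higher and 3199 lower under U0126, or 3652 and 1785 with median centring, and 1192 of them at least 2-fold (700 higher, 492 lower). Of 16 milk genes 15 were lower under U0126 than under PP2, with Csn1s1 at −7.62 and Csn2 at least 128-fold lower and dim under U0126, and 23 of 24 G2/M genes were higher (median 1.40, adjusted p = 2.16e-13). The actin ratio was 1.28 ± 0.07 under U0126 and 1.57 ± 0.04 under PP2. All 5 AHR targets were higher under U0126 than under PP2 (median 4.12, adjusted p = 2.48e-07). Interferon genes were not shown to differ between U0126 and PP2 (6 of 14 higher, 3 lower, adjusted p = 0.325). Of the lists called in these contrasts, 8 of 10 and 11 of 13 held with an estimated correlation.

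Many genes were called in the same direction under more than 1 inhibitor. The pairs ran from 1757 genes for DAPT and U0126 (809 higher, 948 lower) to 2762 for DAPT and PP2 (1305 higher, 1457 lower). With median centring these were 286 higher and 1054 lower, and 383 and 1950, and TAE226 and PP2 shared most (176 higher, 2792 lower). Independent lists of those sizes would share 380 and 427 for the first pair and 509 and 534 for the second. Simulated unchanged groups shared at most 1 gene in any pair, but few genes can be called where no group changes. That count therefore does not show how many shared calls the common vehicle arrays add. For U0126 and PP2, 2079 genes moved the same way and 954 in opposite ways. Across genes, the correlation of fold changes was 0.348 for U0126 and PP2 and 0.647 for DAPT and PP2, against simulated values of 0.501 and 0.496. It was 0.495 for DAPT and U0126 and 0.500 for TAE226 and PP2, against 0.502 and 0.497. TAE226 had 0.615 with DAPT and 0.612 with U0126, against 0.502 and 0.504. The simulated groups differed by noise alone, much of it from the shared vehicle arrays. Their correlation is therefore no baseline for groups with real changes, and neither an excess nor a lack of sharing can be read from it. The covariances for U0126 and PP2 and for DAPT and PP2 were 0.153 and 0.237, against 0.016 and 0.0159 from the shared vehicle arrays alone. The lowest of all pairs was 0.138 (DAPT and TAE226), against 0.0161. The 3 vehicle arrays could not be divided into parts of at least 2 each, so part of the excess may come from them. All 4 inhibitors raised 403 genes, where independent lists would share 15.0, and lowered 583, where they would share 18.2, or 95 and 809 with median centring. The genes lowered held, with either scaling, all 14 interferon response genes. Without centring they also held members of the unfolded protein and integrated stress response list, such as Ddit3 and Trib3. Cholesterol synthesis genes such as Cyp51 and Sqle were among them as well. Both of these lists were called lower under all 4 inhibitors with the preset correlation. For changes shared by all 4, a state of the vehicle cultures and an effect of the inhibitors cannot be told apart.

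Markers of other cell types were mostly dim. Among genes above the array median on at least 3 arrays were 3 of 11 fibroblast markers, 4 of 12 macrophage markers, 1 of 9 endothelial markers, and 0 lymphocyte or adipocyte markers. Postn and the receptor Cd14 lay above it on all 15 arrays, with vehicle means of 13.81 and 13.48. Both genes also moved, Postn under PP2 (−5.30, adjusted p = 1.18e-16) and Cd14 under U0126 (−2.51). In vehicle Col1a1, Col3a1 and Dcn were dim (4.92, 4.25 and 3.55), as were Lyz2, Tyrobp and C1qa (4.79, 3.89 and 1.67). Of the other members of those lists, only Mmp2 (6.65) and Cd68 (6.38) lay above the median on all vehicle arrays. Postn and Cd14 therefore do not by themselves mark fibroblasts or macrophages here, and the cells they came from were not tested. Arrays centred on their medians moved the median of all genes by −0.133 under DAPT, −0.0823 under U0126, −0.254 under TAE226 and −0.219 under PP2. The splits of higher against lower genes changed with it, while changes of the lists described as called kept their direction apart from the BCL2 family under TAE226.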

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

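No added alternatives were run, and the cause was not tested for the changes given here except where it follows from the setting. Among the 332 fold changes of genes named by the rule, those called kept their direction under each alternative apart from Dll1 under TAE226 (−7e-04 with median centring) and Dtx1 under TAE226 (0.0516 as the mean of its probe sets). For 62 fold changes of genes considered outside the rule, of which 47 were called, only both other scalings were run. Quantile normalization ended 0 of these calls, and median centring ended 4 (Egfr, Erbb2 and Erbb3 under PP2 and Klk1b1 under TAE226) and turned Erbb3 (−0.0059). Both scalings added a call for Foxj1 under PP2, as a fall. Calls of genes named by the rule ended in 17 cases with median centring, in 31 with the mean of a gene's probe sets and in 44 with 1 array left out. Of the 104 tests of lists, 14 calls ended with an estimated correlation and 5 with 1 array left out. The number of arrays limits the precision, and for genes below the array median in a group only a bound on the fold could be given, since MAS5 signals there are mostly background.

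Counts that moved by more than 1.5 times followed from the setting. With a 2-fold minimum, calls were 434 (DAPT), 650 (U0126), 322 (TAE226) and 1040 (PP2) against vehicle, 809 for TAE226 and PP2, 426 for U0126 and TAE226, and 1192 for U0126 and PP2. Genes shared at that size were 207 (DAPT and U0126), 157 (DAPT and TAE226), 264 (DAPT and PP2), 206 (U0126 and TAE226), 245 (U0126 and PP2) and 169 (TAE226 and PP2). Testing all probe sets singly gave 7280, 8205, 7066 and 12074 probe sets against vehicle, 8728, 7824 and 12326 for the contrasts in the same order, and 16335 among the 5 groups. With an estimated correlation 9 lists were called under DAPT. Fry, which does not compare a list with other genes, called 21 (U0126), 24 (TAE226) and 26 (PP2).

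Leaving out 1 array at a time gave 3157 to 3507 genes for DAPT, 4096 to 4316 for U0126, 2883 to 3174 for TAE226 and 5356 to 5876 for PP2. It gave 4327 to 4508 for TAE226 and PP2, 3557 to 3928 for U0126 and TAE226, 5736 to 6031 for U0126 and PP2, and 7915 to 8327 among the 5 groups. Lists called were 13 to 15 (DAPT), 11 to 11 (U0126), 13 to 14 (TAE226) and 13 to 14 (PP2).

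Replicate numbers are shared between groups, but arrays with the same number did not deviate together (r from −0.238 to 0.200, mean −0.0102), and 4 of 15 arrays correlated best with their own number. With the replicate block, 3794 (DAPT), 4517 (U0126), 3409 (TAE226) and 5930 (PP2) genes were called against vehicle. The contrasts had 4846, 4063 and 6232, the 5 groups 8160, and the lists 15, 11, 13 and 13.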

Other observations

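Members of the kallikrein family Klk1b, secreted proteases of gland ducts, rose under DAPT and PP2, and the family was not tested as a list. Of 8 members tested, 7 rose under DAPT and 8 under PP2. The 5 members above the dim level in vehicle changed by 2.57 to 4.34 under DAPT (median 2.72) and 2.02 to 4.45 under PP2 (median 3.10). Under TAE226 3 rose, 1 of them dim in both groups, and under U0126 2 fell, 1 of them to a dim level. These genes are near-identical copies, so signal can pass between their probe sets and each single value is uncertain, as for Egfbp2 (4.34 under DAPT and 4.45 under PP2), which is read by a probe set marked for cross-hybridisation.

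Some genes outside the lists were among the greatest changes in this series, and the values given for them in further comparisons were chosen after they were seen. Mal rose under all 4 inhibitors, by 2.97 (DAPT), 6.45 (U0126), 3.07 (TAE226) and 2.12 (PP2). Sox11, a transcription factor of embryonic neural cells, rose under U0126 (4.47) and TAE226 (2.67) and fell at least 1.17-fold to a dim level under PP2 (adjusted p = 0.000123). The keratin Krt15 rose under DAPT (3.97) and fell at least 2.97-fold to a dim level under U0126. Gad1, which makes the transmitter GABA, fell to a dim level under all 4 inhibitors, at least 4.15-fold (DAPT), 4.3-fold (U0126), 3.82-fold (TAE226) and 3.91-fold (PP2). Foxj1 rose under DAPT (1.39), U0126 (3.18) and TAE226 (2.93), with −0.23 under PP2 (adjusted p = 0.103). Under PP2 it passed as a fall with quantile normalization (−0.37, adjusted p = 0.0188) and with median centring (−0.45, adjusted p = 0.0136).

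The tests of the interferon and AHR patterns and of the luminal share were chosen after those results were seen, and those of RNA quality, of motile cilia and of the splits before. A motile cilia programme was a hypothesis for the rise of Foxj1. Of 25 cilia genes only 4 were tested, below the minimum of 5. The smaller of the p-values was 0.0178, under TAE226 (3 of 4 rose, unadjusted camera p, and 0.0369 with an estimated correlation), and under U0126 p was 0.166 (2 of 4 rose), so the hypothesis stays undecided for want of measured members.

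Interferon response genes were lower under all 4 inhibitors. Array scaling is argued against, since the list median nearest to 0 over the 4 comparisons and both other scalings was −2.15. Fewer immune cells are argued against only by a choice of 9 abundant immune genes. Their highest vehicle mean signal was 40.8 (Fcer1g), below the lowest array median of 65.7. Those 9 leave out Csf1r, above the median on 2 of 3 vehicle arrays (mean log2 signal 6.26), whose mean was no lower under any inhibitor (6.30 to 6.81). Of 2 further genes from the macrophage list, above the median on all vehicle arrays, Cd68 passed in none of the 4 comparisons (adjusted p = 0.0547 to 0.651). Cd68 was, however, dim under DAPT (−0.53), TAE226 (−0.34) and PP2 (−0.68). Cd14 fell under U0126 (−2.51), TAE226 (−0.67) and DAPT (−0.39), but was at 0.02 under PP2 (adjusted p = 0.752), where interferon genes also fell. A state of the vehicle cultures as the whole cause is argued against by the median difference of 1.66 between TAE226 and PP2, or 1.13 with 4 members dim under PP2 at their bound and 2 dim in both left out. Of the 8 members above the dim level in both groups, 7 were higher under TAE226 (unadjusted camera p = 9.94e-06, and 0.0158 with an estimated correlation). The other inhibitors lay closer together, with bounded medians of −3.02 (DAPT), −2.82 (U0126) and −2.83 (PP2). The bounded median difference between U0126 and PP2 was 0.24, and the list was not shown to differ there, as a state of the vehicle cultures would also give. Whether such a state lies behind the part shared by all 4, whose smallest median was −2.13, and an effect of the inhibitors cannot be told apart, because there was only 1 vehicle group.

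AHR targets were higher under U0126. Array scaling is argued against by a list median of 5.50 under the lower of both other scalings. The list's median difference between U0126 and PP2 was 4.12. The ERK outputs' median was as low under PP2 (−0.99, or −0.92 with dim members at their bound) as under U0126 (−0.85). These values argue against loss of ERK output to that depth only if PP2 has no effect of its own on AHR targets, which was not tested. Cyp1b1 and Aldh3a1 were called higher under PP2 too, as under each inhibitor, although the list was not called there. A deeper loss under U0126 stays open, because 2 of 17 outputs, Egr1 (−1.74) and Phlda1 (−1.16), were lower under U0126 than under PP2, while 11 were higher. Binding of U0126 itself to the receptor is a possible explanation that no group here tests, as there was no second MEK inhibitor.

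Milk and alveolar genes were higher under PP2 and lower under U0126. A trend with the actin 3′ to 5′ ratio and an effect of PP2 cannot be told apart. The list median under PP2 was 0.71 with that ratio as a covariate and 1.06 without it, and camera still called the list (p = 1e-06, and 0.00232 with an estimated correlation). The bound set for this test was wrong, however, because limma called 0 genes for the ratio itself (502 at an unadjusted p under 0.05, where 571 are expected by chance). The correction was therefore poorly estimated, and each PP2 array had a higher ratio than the arrays of the other groups. Across groups the ratio went with the milk median under U0126 (1.28, with −0.87) and against it under DAPT (1.35, with 0.67), as vehicle had 1.42, and TAE226 had 1.33 with a median of −0.10. The Gapdh ratio was 0.777 in vehicle, 0.827 in PP2, 0.791 in U0126, 0.801 in DAPT and 0.793 in TAE226, so it was higher in PP2, like that of actin, but not lower in U0126. Other probe sets moved the same way in 100% of cases, but only 3 were bright, too few to weigh. A larger share of luminal cells stays open, since the median of 13 luminal markers was 0.0741 with an SD of 1.01, which reaches the milk median. That SD is the spread between markers and not the error of their median, and the luminal list was not called under PP2. The rule for this test was narrowed after the value was seen. An effect of Src inhibition on milk genes stays open beside these.

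Other splits of the same arrays were counted for each result. For the F-test over 5 groups, 1 of 100 splits, the real one with 8351 genes, was as large, and the highest of the others gave 1189, so chance is argued against for that count. In a comparison of 3 against 3 arrays there are only 10 splits, too few for a share below 0.05, and 1 of them, the real one, was as large for each count that follows. Each other split mixed arrays of both treatments on each side. The treatment difference then entered the spread, which lowers the gene counts, and part of it stayed in the contrast, so those splits are not unchanged groups. Genes called were 3948 (DAPT), 4663 (U0126), 3548 (TAE226) and 6030 (PP2), with highest other values of 0, 1, 0 and 0. The contrasts had 4975 (TAE226 and PP2), 4249 (U0126 and TAE226) and 6375 (U0126 and PP2), against 1, 0 and 0. Lists called were 15, 11, 13 and 13 for DAPT, U0126, TAE226 and PP2, against 9, 9, 11 and 10 in the highest other split. With an estimated correlation they were 9, 9, 9 and 11, against 0 in each.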
